A study of Mus musculus with 43 samples.

How the data were processed

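Expression values are FPKM made by the authors, per the file headers and the values, with reads processed with TopHat2 2.0.11 and CASAVA and with the builds mm9 and mm10 named in the submitters' processing notes without a role for either. Whether the authors scaled the FPKM between libraries, and which program computed them, is not given in the sources used here. Counts of mapped reads per library were deposited for 19 libraries, and the fraction of reads that mapped was deposited beside them, per the file headers. The ChIP-seq regions were called by the authors with MACS 1.4.2 at a p cutoff of 1e-05, per the file headers, from 1894382 filtered tags of the DDX18 library and 1571390 of the control. The deposited tag counts per region, the fold enrichment (a ratio to the local control background), the percent false discovery rate and the score (taken from its place in the table as -10 times log10 of the p-value, its name being lost) are those of that program, per the file headers. The headers call the control library igg, while the labels describe BirA cells. The CLIP and TAP regions carry a score per region made by the authors, whose meaning, like the region caller and its filter, is not given in the sources used here; they were annotated with annotatePeaks.pl on mm10, per the file headers.

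Libraries were assigned to groups from the labels and the column names of the 8 expression tables. Where a symbol occurred more than once, which concerned 171 entries at most in a table of 46683 symbols, the entry with the highest mean was kept. Up to 25 symbols per table had been turned into dates and could match no gene list. Of the 594 pairs of libraries in different tables, 0 shared most of their values, equal meaning within 0.1%, so no library recurs between tables. Each expression table has 1 gene entry that was not analysed here.

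Each comparison was tested with limma 3.58.1 on log2(FPKM + 1) with a variance trend, over genes with an FPKM of at least 1 in as many libraries as the smallest group holds, two-sided, with Benjamini-Hochberg adjustment and an adjusted p under 0.05. The groups of 1 table entered the same fit, so the ActD doses share a spread and their control libraries. None of the expression tables held counts. The difference of an effect between genotypes was fitted over both tables with 1 mean per group, so that only differences within a table entered it. With so few libraries no exact permutation test could pass, so the p-values rest on limma's pooled spread.

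The 25 gene lists, the tests, the rule for named genes and the alternative settings were written before the data were examined. Choices made later were Fisher's exact test on the knockdown table, the comparison of the EZH2 KO with the p53 KO knockdown, the crossed pairing, the knockdown table's selection rule as an alternative and the symbols of unknown function. They cover the pluripotency network, 2-cell-stage genes, trophectoderm, primitive and parietal endoderm, mesoderm and primitive streak, neuroectoderm and epiblast, p53 targets, ribosomal proteins of the large and of the small subunit, ribosome biogenesis, the RNA polymerase I machinery, PRC2 subunits, Hox genes, the integrated stress response, immediate early genes, snoRNA host genes, S phase, G2 and M phase, apoptosis regulators, fibroblast, blood cell and oocyte transcripts, Y-linked and Xist genes, mitochondrially encoded genes and replication-dependent histone genes. A list with at least 5 tested members was tested with camera at a preset correlation of 0.01, again with the correlation estimated from the residuals, and with fry, adjusted over the lists of a comparison. Camera compares a list with the other genes, and fry tests its genes alone for a shift in 1 direction. Fry passed 20 lists with CX-5461, 16 with knockdown in ESCs, 5 in EZH2 KO, 0 in p53 KO ESCs and 0 in knockout embryos. In the knockdown table, made of selected genes, a two-sided Fisher's exact test set a list's higher and lower members against the other listed genes.

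Named genes follow a rule that takes Ddx18, Trp53 and Ezh2 in all comparisons. It adds the 6 genes called higher and the 6 called lower with the largest changes, all libraries on 1 side of the controls and a mean of at least 5 FPKM in the higher group. Per list it takes up to 4 called members with the largest changes or, where none was called, the 2 with the highest mean. Predicted genes and 12 symbols of unknown function were left out. For regions the rule takes the 10 with the highest score or fold enrichment and the ribosomal, small nucleolar and small nuclear RNA classes. Other genes were chosen after their values were seen, and the text says so.

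The knockdown table in ESCs lists only part of the genes, and all of them pass, at the 0.05 level, a comparison of both groups' FPKM with equal variances and reach an FPKM of 1 in some library. This rule was found by testing the table and is not stated by the authors. CLIP and TAP regions were counted per annotation class and compared between libraries by an overlap of at least 1 base on the same strand. The fits were tested on simulated data with 200 changed genes on the real group sizes. At a change of 2-fold they recovered 82.1% of the changed genes for the knockdown in EZH2 KO ESCs, 55.2% for 10 ng/ml ActD in ESCs, 86.6% for CX-5461 and 1.49% for the embryos, and at 4-fold 98.5%, 84.8%, 98.5% and 33.3%. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.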

Results

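The series comprised 43 mouse samples, 37 of them RNA-seq libraries of embryonic stem cells (ESCs) or of E3.5 embryos. In ESCs grown in serum with LIF, 2 libraries with knockdown of Ddx18, which encodes a DEAD-box RNA helicase of the nucleolus, were set against 2 control libraries, and the same design was repeated with 2 against 2 libraries in p53 KO and in EZH2 KO ESCs. Embryos at E3.5, the day of the blastocyst stage in normal development, gave 2 wild-type and 2 Ddx18 knockout libraries. ESCs without treatment (3 libraries) were compared with ESCs given ActD at 5 or 10 ng/ml (2 libraries each), and p53 KO ESCs with 0 and 10 ng/ml ActD had 2 libraries each. CX-5461, an inhibitor of RNA polymerase I transcription, was given at 1 µM (3 libraries against 3), and CHX at 10 µM (2 against 2). Binding was measured in ESCs that carry tagged DDX18 by ChIP-seq (1 library and 1 library of BirA control cells), by CLIP-seq (2 libraries) and by TAP-seq (2 libraries), the last a variant of CLIP with a tandem purification.

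The 19 RNA-seq libraries with read totals held 7112852 to 22983179 mapped reads, and depth is unknown for the embryo, CX-5461, p53 KO knockdown and EZH2 KO knockdown libraries. Values are FPKM, given as mean ± SD over the libraries of a group, with n as stated above. Changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values, and a gene that rose or fell passed an adjusted p of 0.05 in limma. Every gene given with an adjusted p under that threshold had all treated libraries on 1 side of all control libraries. The p-values measure the spread between these libraries, and nothing in the labels tells separate cultures or embryos from technical repeats. Where a library lists a gene at 0, the values are given library by library instead. Rescaled values come from the same data after each library was divided by its median ratio to the geometric mean library.

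The first comparison addressed what DDX18 does in ESCs. Knockdown lowered Ddx18 from 86.9 ± 3.15 to 9.23 ± 1.00 FPKM (log2 change -3.11, adjusted p = 2.6e-06); this gene has the identifier ENSMUSG00000001674.11 and lies on chromosome 1 from 121553834 to 121567989 in mm10. The 2 knockdown libraries also held more of the secreted matrix protein gene Cyr61 (from 9.08 ± 0.198 to 110.3 ± 5.33 FPKM, log2 change 3.46). The lactate transporter gene Slc16a3 fell from 44.3 ± 0.395 to 3.34 ± 0.583 FPKM, the mitophagy receptor gene Bnip3 from 17.02 ± 1.12 to 1.25 ± 0.316 FPKM and the glycolytic enzyme gene Tpi1 from 204 ± 3.79 to 32.9 ± 3.20 FPKM. Trp53 stood at 384 ± 11.5 without and 437 ± 8.17 FPKM with knockdown (log2 change 0.19), a value that turned to -0.13 after rescaling, and Ezh2 fell from 55.2 ± 1.61 to 36.4 ± 4.50 FPKM.

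All 31 listed p53 target genes were higher with knockdown (Fisher's exact test against the other listed genes, adjusted p = 1.0e-07), a test used for all lists of this table that treats genes as independent; camera gave an adjusted p = 0.2 with an estimated correlation. The kinase gene Plk2 rose from 14.8 ± 0.417 to 86.2 ± 6.73 FPKM, the membrane protein gene Perp from 14.3 ± 0.504 to 82.0 ± 7.83 FPKM and the antiproliferative gene Btg2 from 12.4 ± 1.401 to 62.5 ± 3.01 FPKM. Among genes chosen after their values were seen, the cell cycle inhibitor gene Cdkn1a rose from 26.0 ± 0.917 to 86.5 ± 0.861 FPKM and the p53 ubiquitin ligase gene Mdm2 from 45.3 ± 0.584 to 163 ± 13.5 FPKM. Of the 17 listed genes of the pluripotency network, 14 were lower and 3 higher (adjusted p = 0.005; camera adjusted p = 0.2 with an estimated correlation), with falls in the Nodal antagonist gene Lefty2 (from 49.4 ± 1.37 to 11.7 ± 2.75), the Nodal co-receptor gene Tdgf1 (from 335 ± 1.68 to 141 ± 3.86) and Fgf4 (from 34.4 ± 0.604 to 15.6 ± 0.424). Nanog and Pou5f1, transcription factor genes of the network chosen after their values were seen, fell from 150.4 ± 1.84 to 85.5 ± 1.27 FPKM and from 474 ± 8.02 to 361 ± 4.27 FPKM. Genes of the 2-cell stage were higher in 12 of 13 cases (adjusted p = 0.018; camera adjusted p = 0.2 with an estimated correlation), and those with the largest changes were deubiquitinase genes of the Usp17l family, whose near-identical copies can share reads, at log2 changes of Usp17la (2.03), Usp17lb (1.91) and Usp17le (1.39). Trophectoderm genes were higher in 11 of 12 cases (adjusted p = 0.028; camera adjusted p = 0.2 with an estimated correlation), with Krt18 (from 8.69 ± 0.0909 to 58.1 ± 9.17), Hand1 (from 2.04 ± 0.185 to 12.7 ± 0.654) and Krt8 (from 15.5 ± 0.861 to 68.4 ± 14.1) FPKM.

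All 41 listed genes of the large and all 23 of the small ribosomal subunit were lower (adjusted p = 1.9e-14 and 2.4e-08; camera adjusted p = 0.2 with an estimated correlation), such as Rpl3 (from 849.6 ± 21.1 to 510.4 ± 27.03). Ribosome biogenesis genes were lower in 40 of 41 cases (adjusted p = 5.2e-13; camera adjusted p = 0.21 with an estimated correlation), among them the nucleolar factor genes Nolc1 (from 169 ± 6.33 to 86.9 ± 4.02) and Tcof1 (from 81.5 ± 5.11 to 49.96 ± 0.501). All 18 S-phase genes and all 15 replication-dependent histone genes were lower (adjusted p = 9.8e-07 and 1.0e-05; camera adjusted p = 0.21 and 0.22 with an estimated correlation), with Ccne1 (from 119 ± 3.15 to 43.6 ± 1.15) for cyclin E1. Immediate early genes were higher in 12 of 14 cases (adjusted p = 0.0473; camera adjusted p = 0.2 with an estimated correlation) and G2 and M phase genes lower in 11 of 13 (adjusted p = 0.0074; camera adjusted p = 0.2 with an estimated correlation). The 6 listed PRC2 genes went both ways (2 higher, 4 lower, adjusted p = 0.44), with the catalytic subunit gene Ezh2 lower and the accessory gene Phf1 higher (from 2.00 ± 0.123 to 6.78 ± 1.07 FPKM). The integrated stress response list also went both ways, with Ddit3, a transcription factor gene, higher (from 6.53 ± 1.00 to 45.6 ± 6.76) and Chac1, a glutathione-degrading enzyme gene, lower (from 8.14 ± 1.03 to 1.72 ± 0.299), and its median of -0.62 lay apart from its mean of -0.04.

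The knockdown table held 4769 genes, 2699 higher and 2070 lower, all chosen by the authors on these same 4 libraries. Its lists are thus not independent evidence of direction, and unlisted genes were not analysed. That selection enters limma's p-values and count of 4595 of 4695 tested genes. The median over these genes was 0.30 as deposited and 0.02 rescaled, and the lists are to be read against that shift. The p53 targets had medians of 1.14 and 0.84, the pluripotency network -0.59 and -0.90 and ribosome biogenesis -0.36 and -0.66. With camera, 11 of 16 lists passed, and none held with an estimated correlation.

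**Figure D1:**
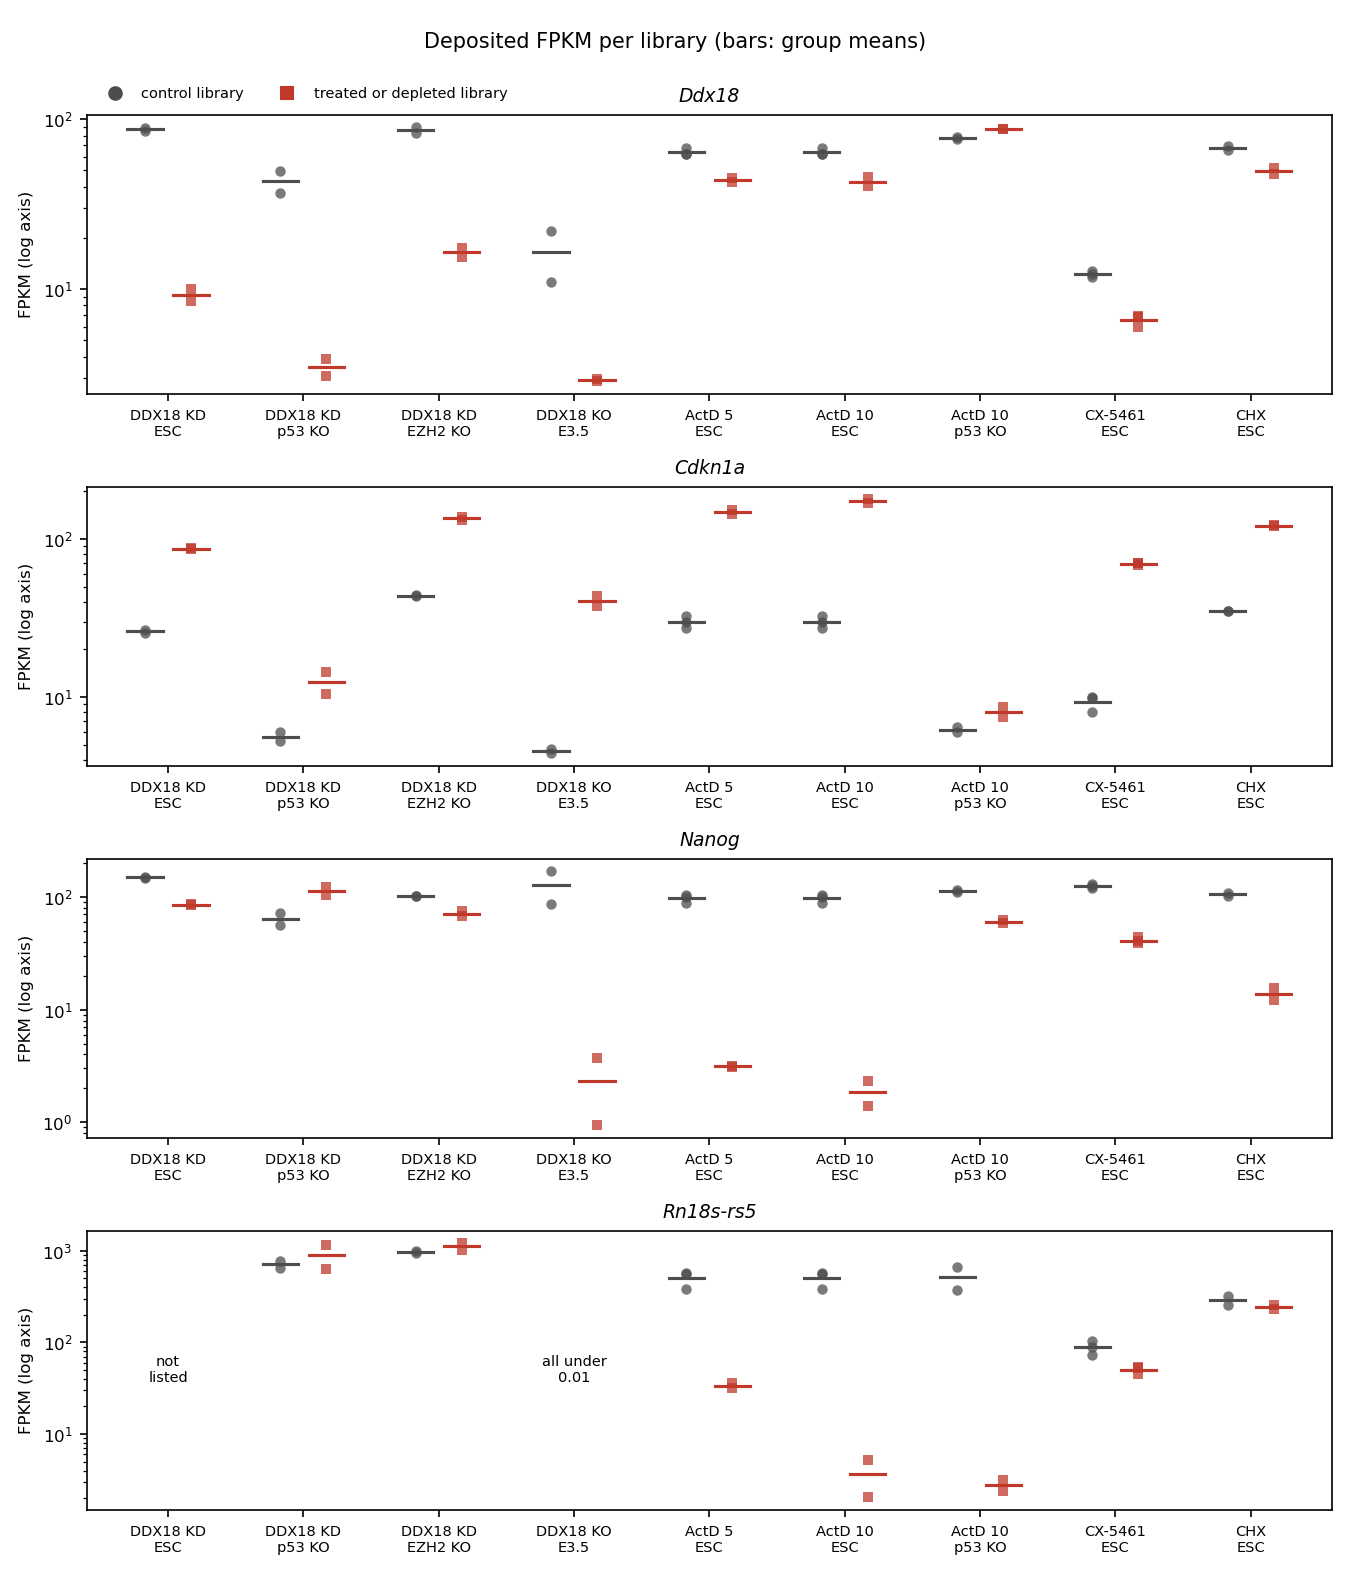
FPKM per library on a log axis for Ddx18, Cdkn1a, Nanog and Rn18s-rs5 in the 9 comparisons, with control libraries and treated libraries as points and group means as bars. Ddx18 was lower in all 8 libraries with knockdown or knockout than in their controls, and Rn18s-rs5 went from 501 to 3.64 with ActD at 10 ng/ml in ESCs.

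Knockdown in EZH2 KO ESCs asked whether the response to loss of DDX18 passes through PRC2, whose catalytic subunit is EZH2. The Ezh2 transcript stood at 3.52 ± 0.844 without and 3.30 ± 0.771 FPKM with knockdown, and Ddx18 fell from 86.0 ± 4.88 to 16.5 ± 1.37 FPKM (log2 change -2.32, adjusted p = 0.0018). Cyr61 rose from 12.9 ± 1.82 to 94.0 ± 3.31 FPKM and Cpz from 3.25 ± 0.281 to 37.9 ± 2.30 FPKM, while Slc16a3 fell from 51.0 ± 0.0132 to 15.6 ± 3.37 FPKM. Cdkn1a rose from 43.9 ± 0.363 to 135 ± 4.44 FPKM, Btg2 from 10.2 ± 0.692 to 46.1 ± 2.69 FPKM and Perp from 22.8 ± 2.62 to 92.4 ± 8.74 FPKM. Nanog fell from 102 ± 0.817 to 71.2 ± 5.10 FPKM.

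Of the 37 tested p53 targets, 15 rose and 22 did not pass (23 higher and 1 lower adjusted over the list alone). Their median log2 change was 0.58 (camera adjusted p = 9.9e-09, adjusted p = 0.23 with an estimated correlation). Among the 30 tested pluripotency genes, 4 fell and 26 did not pass (11 lower adjusted over the list alone). They include Fgf4 (-0.78). The median was -0.24 (camera adjusted p = 1.4e-06, adjusted p = 0.27 with an estimated correlation). Of the 19 tested trophectoderm genes, 6 rose, 1 fell and 12 did not pass (10 higher and 1 lower adjusted over the list alone). They include Hand1 (from 2.66 ± 0.884 to 16.02 ± 1.00) and Krt18 (from 10.6 ± 0.832 to 37.7 ± 1.17). The median was 0.70 (camera adjusted p = 0.0052, adjusted p = 0.39 with an estimated correlation). Of the 46 tested large-subunit ribosomal protein genes, 7 fell and 39 did not pass (16 lower adjusted over the list alone). They include Rpl10a (from 868 ± 5.11 to 559 ± 34.6). The median was -0.25 (camera adjusted p = 1.5e-11, adjusted p = 0.23 with an estimated correlation).

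Of the 83 tested ribosome biogenesis genes, 6 fell and 77 did not pass (6 lower adjusted over the list alone). They include Nolc1 (from 190.0 ± 12.4 to 118 ± 4.68) and Tcof1 (from 139 ± 3.23 to 91.1 ± 1.82). The median was -0.09 (camera adjusted p = 1.0e-05, adjusted p = 0.39 with an estimated correlation). Of the 23 tested S-phase genes, 5 fell and 18 did not pass (1 higher and 13 lower adjusted over the list alone). They include Pcna (from 140.0 ± 8.83 to 84.1 ± 5.62). The median was -0.38 (camera adjusted p = 3.4e-08, adjusted p = 0.23 with an estimated correlation). Of the 12 tested PRC2 genes, only E130012A19Rik, an accessory subunit gene, passed (from 739 ± 8.10 to 439.6 ± 25.8 FPKM; 1 lower adjusted over the list alone). Of 11773 genes tested, 999 passed, 742 higher and 257 lower (3220 at an unadjusted p under 0.05), and 74.3% of the called genes were higher as deposited and 52.2% after rescaling. Some calls held without either control library, and none without either knockdown library. Such a fit leaves 1 library in a group, so calls lost there do not tell dependence on a library from the smaller design.

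The same knockdown in p53 KO ESCs asked which part of the response needs p53. Trp53 transcript remained in these cells at 119 ± 9.35 without and 227 ± 45.7 FPKM with knockdown (log2 change 0.91, adjusted p = 0.063), and Ddx18 fell from 43.3 ± 9.08 to 3.47 ± 0.555 FPKM (log2 change -3.30, adjusted p = 0.0481). The transcription factor gene Tfap2c rose from 13.5 ± 0.274 to 66.6 ± 6.50 FPKM, its paralog Tfap2a from 2.04 ± 0.0518 to 11.8 ± 4.12 FPKM and Otx2, a factor of the epiblast, from 10.6 ± 0.208 to 41.3 ± 15.6 FPKM. Gbx2 and Etv4, transcription factor genes, fell from 53.05 ± 5.80 to 9.04 ± 1.87 FPKM and from 42.4 ± 3.22 to 7.42 ± 3.51 FPKM, Myc from 113 ± 10.8 to 25.3 ± 11.3 FPKM and the nucleolar factor gene Tcof1 from 167 ± 30.2 to 50.6 ± 2.68 FPKM.

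No p53 target of the 29 tested passed limma, over all genes or adjusted over the list alone, and 4 were higher at an unadjusted p under 0.05. Their median log2 change was 0.20 as deposited and -0.17 rescaled (camera adjusted p = 0.77, adjusted p = 0.77 with an estimated correlation), so that its sign depended on the scaling and the camera direction was down. Cdkn1a and Mdm2, chosen after their values were seen, stood at 5.61 ± 0.525 without and 12.4 ± 2.79 FPKM with knockdown (adjusted p = 0.07) and 9.42 ± 0.347 without and 18.6 ± 0.701 FPKM with knockdown (adjusted p = 0.061). Among the 30 tested pluripotency genes, 2 fell and 28 did not pass (6 higher and 2 lower adjusted over the list alone). They include Gbx2 and L1td1 (from 182 ± 6.37 to 61.3 ± 4.86). The median was 0.16 as deposited and -0.24 rescaled (camera adjusted p = 0.23, adjusted p = 0.75 with an estimated correlation), with a mean of 0.03 and a camera direction of down. Nanog and Pou5f1, chosen after their values were seen, stood at 64.5 ± 11.6 without and 113 ± 12.4 FPKM with knockdown (log2 change 0.81, adjusted p = 0.074) and 1005 ± 41.8 without and 1315 ± 284 FPKM with knockdown (log2 change 0.37, adjusted p = 0.3). None of the 10 tested 2-cell-stage genes passed limma, and none did at an unadjusted p under 0.05; their median was -0.32 as deposited and -0.52 rescaled (camera adjusted p = 0.0063, adjusted p = 0.75 with an estimated correlation).

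Of the 83 tested ribosome biogenesis genes, 1 fell and 82 did not pass (1 lower adjusted over the list alone). They include Tcof1. The median was 0.22 as deposited and -0.18 rescaled (camera adjusted p = 0.25, adjusted p = 0.75 with an estimated correlation), with camera pointing down. Of the 14 tested Hox genes, 1 rose and 13 did not pass (3 higher adjusted over the list alone). They include Hoxc13 (from 0.812 ± 0.244 to 4.71 ± 0.379). The median was 0.88 as deposited and 0.66 rescaled (camera adjusted p = 0.017, adjusted p = 0.74 with an estimated correlation). Of the 13 tested mitochondrially encoded genes, 2 fell and 11 did not pass (5 lower adjusted over the list alone). They include mt-Nd1 (from 169.8 ± 8.18 to 72.5 ± 2.12). The median was -0.33 as deposited and -0.74 rescaled (camera adjusted p = 7.7e-08, adjusted p = 0.75 with an estimated correlation). Of 11636 genes tested, 380 passed, 306 higher and 74 lower (3628 at an unadjusted p under 0.05). The median of all genes was 0.34 as deposited and 0.01 after rescaling, and 80.5% of the called genes were higher as deposited and 20.5% after rescaling. A fit without 1 of the 4 libraries leaves 1 library in a group. Calls lost there do not tell dependence on a library from the smaller design. No call held in any of these fits. No call held either with a pseudocount of 0.1, no filter or no variance trend (limma, 0 genes each; 3536, 4009 and 3585 at an unadjusted p under 0.05), while 868 genes passed at a minimum of 5 FPKM and 151 rescaled, Tfap2a, Otx2 and Hoxc13 not among the latter.

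The difference of the knockdown effect between genotypes was tested gene by gene. Log2 changes in ESCs and in p53 KO ESCs were 2.25 against 0.04 (adjusted p = 0.0081) for Btg2, 2.46 against 0.05 (adjusted p = 0.0087) for Plk2, 2.44 against 0.69 (adjusted p = 0.009) for Perp and 3.46 against 1.14 (adjusted p = 0.004) for Cyr61. For Mdm2, Nanog and Pou5f1, chosen after their values were seen, they were 1.82 against 0.91 (adjusted p = 0.0097), -0.81 against 0.81 (adjusted p = 0.0054) and -0.39 against 0.37 (adjusted p = 0.045). The p53 targets lay higher in ESCs by a median of 0.89 (camera adjusted p = 3.0e-12, adjusted p = 0.037 with an estimated correlation), with 19 of 31 members called. The pluripotency network lay lower in ESCs by a median difference of -0.76 (camera adjusted p = 0.043, adjusted p = 0.24 with an estimated correlation), with 9 of 17 members called below and 2 above. The 2-cell-stage genes differed by 1.06 (camera adjusted p = 5.5e-05, adjusted p = 0.15 with an estimated correlation) and ribosome biogenesis by -0.50 (camera adjusted p = 0.0018, adjusted p = 0.24 with an estimated correlation). In all, 1164 of 4707 genes differed (557 above and 607 below in ESCs).

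Between ESCs and EZH2 KO ESCs, 987 of 4706 genes differed (490 above and 497 below in ESCs). The knockdown itself was deeper in ESCs, with log2 changes of Ddx18 of -3.11 against -2.32 (adjusted p = 0.013). Bnip3 had -3.01 against -0.82 (adjusted p = 0.011), Lefty2 -2.01 against -0.32 (adjusted p = 0.0037) and Plk2 2.46 against 1.34 (adjusted p = 0.0036). The median difference over a list's genes was 0.51 (camera adjusted p = 5.7e-07, 0.13 with an estimated correlation) for p53 targets. It was -0.30 (camera adjusted p = 0.024, 0.18 with an estimated correlation) for the pluripotency network. It was 0.67 (camera adjusted p = 0.0015, 0.13 with an estimated correlation) for 2-cell-stage genes. It was -0.23 (camera adjusted p = 3.8e-04, 0.23 with an estimated correlation) for ribosome biogenesis. Rescaled, these were 0.32, -0.49, 0.44 and -0.42. In a comparison added after the data were seen, 178 of 12506 genes differed between the knockdowns in EZH2 KO and p53 KO ESCs, with log2 changes of 2.07 against 0.04 (adjusted p = 0.0456) for Btg2, -0.51 against 0.81 (adjusted p = 0.0456) for Nanog, -0.95 against 1.82 (adjusted p = 0.028) for Otx2 and 0.01 against -2.44 (adjusted p = 0.022) for Gbx2. The ESC knockdown genes were selected by a test that favours larger effects and smaller spread there, so p-values against ESCs can be too small. Genotype and table coincide throughout.

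Knockout embryos addressed what DDX18 does in the blastocyst. Ddx18 fell from 16.5 ± 7.75 to 2.91 ± 0.0745 FPKM (log2 change -2.09, adjusted p = 0.045). Nanog fell from 128 ± 58.1 to 2.32 ± 1.96 FPKM (log2 change -5.34, adjusted p = 0.023). The keratin genes Krt8 and Krt18, markers of the trophectoderm, fell from 88.5 ± 9.41 to 9.41 ± 1.43 FPKM and from 64.3 ± 3.88 to 10.7 ± 1.72 FPKM. The homeobox gene Obox6 and the tripartite motif gene Trim43b, which are active in the early embryo, rose from 8.98 ± 7.17 to 71.1 ± 9.12 FPKM and from 27.9 ± 25.9 to 197 ± 5.66 FPKM. Cdkn1a rose from 4.54 ± 0.210 to 40.6 ± 4.11 FPKM (adjusted p = 0.023). Genes used in all cells moved too: the tubulin gene Tubb5 fell from 119 ± 2.90 to 4.17 ± 2.84 FPKM, and Actb, chosen after its values were seen, from 969.9 ± 21.2 to 201 ± 38.7 FPKM. Gapdh and Ldha, chosen after their values were seen, were listed at 2.40, 2.14, 0.248 and 0 FPKM and at 0.231, 0, 0 and 0.810 FPKM in the 2 wild-type and then the 2 knockout libraries. The mitochondrial gene mt-Nd2 rose from 1956 ± 311 to 3998 ± 576 FPKM. The number of genes at 1 FPKM or more was 8829, 8387, 7655 and 7722 in the same order, lower in both knockout libraries, and a difference in RNA quality or amount between the groups was not tested.

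Among the 24 tested pluripotency genes, 2 fell and 22 did not pass (8 lower adjusted over the list alone). They include L1td1 (from 22.6 ± 7.62 to 4.78 ± 1.71). The median was -0.59 as deposited and -0.28 rescaled (camera adjusted p = 0.23, adjusted p = 0.53 with an estimated correlation). Pou5f1, chosen after its values were seen, stood at 14.7 ± 5.39 without and 11.3 ± 7.37 FPKM with knockout with overlapping libraries (adjusted p = 0.62). Of the 10 tested trophectoderm genes, 3 fell and 7 did not pass (4 lower adjusted over the list alone). They include Krt8 and Krt18. The median was -0.97 as deposited and -0.72 rescaled (camera adjusted p = 0.024, adjusted p = 0.53 with an estimated correlation). Of the 26 tested p53 targets, 1 rose and 25 did not pass (1 higher adjusted over the list alone). They include Cdkn1a. The median was 0.32 as deposited and 0.55 rescaled (camera adjusted p = 0.0011, adjusted p = 0.53 with an estimated correlation). None of the 8 tested 2-cell-stage genes passed limma (4 were higher at an unadjusted p under 0.05), and their median was 1.32 as deposited and 1.59 rescaled (camera adjusted p = 6.0e-04, adjusted p = 0.42 with an estimated correlation).

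None of the 73 ribosome biogenesis genes passed limma (3 were higher and 3 lower at an unadjusted p under 0.05), and the median was 0.21 as deposited and 0.52 rescaled (camera adjusted p = 1.2e-04, adjusted p = 0.53 with an estimated correlation). Of the 44 tested large-subunit ribosomal protein genes, 1 fell and 43 did not pass (none adjusted over the list alone). They include Rpl3 (from 13.3 ± 2.41 to 3.14 ± 0.658). The median was 0.06 as deposited and 0.42 rescaled (camera adjusted p = 0.02, adjusted p = 0.59 with an estimated correlation), and the mean was -0.02. Of the 27 tested replication-dependent histone genes, 2 rose and 25 did not pass (5 higher and 1 lower adjusted over the list alone). They include Hist1h2ap (from 17.4 ± 5.34 to 57.5 ± 9.98). The median was 0.84 as deposited and 1.11 rescaled (camera adjusted p = 2.7e-06, adjusted p = 0.42 with an estimated correlation). Y-linked Ddx3y was listed at 0 and 8.66 FPKM in the wild-type and at 5.36 and 5.21 FPKM in the knockout libraries (adjusted p = 0.56).

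Of 8687 genes tested, 450 passed, 55 higher and 395 lower (2273 at an unadjusted p under 0.05). The median of all genes was -0.31 as deposited and -0.03 after rescaling, and 12.2% of the called genes were higher as deposited and 33.3% after rescaling. Almost no call held without any 1 of the 4 libraries, but such a fit leaves 1 library in a group. Calls lost there do not tell dependence on a library from the smaller design. With all 4 libraries limma called 3 genes with a pseudocount of 0.1 and 0 with no filter on low values (2756 at an unadjusted p under 0.05). After rescaling 126 genes passed, among them Nanog, Krt8, Krt18, Cdkn1a and Hist1h2ap, while Ddx18, L1td1, Rpl3, Trim43b and mt-Nd2 did not.

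ActD, used in the study to inhibit RNA polymerase I, was set beside the knockdown. Rn18s-rs5, the listed 18S ribosomal RNA gene on chromosome 17 from 39848102 to 39848827, fell from 501 ± 107 to 3.64 ± 2.25 FPKM at 10 ng/ml (log2 change -6.82, adjusted p = 1.7e-05) and, as a gene chosen after its values were seen, from 501 ± 107 to 33.9 ± 3.06 FPKM at 5 ng/ml; in libraries of messenger RNA this reads what ribosomal RNA is left in them. At 10 ng/ml Nanog fell from 97.5 ± 7.80 to 1.85 ± 0.648 FPKM, Tdgf1 from 249 ± 30.6 to 6.96 ± 0.231 FPKM and the orphan receptor gene Esrrb from 115 ± 8.87 to 4.86 ± 0.111 FPKM. The epidermal protein genes Sbsn and Dmkn rose from 0, 2.05 and 1.66 to 306 and 302 FPKM and from 0.621 ± 0.428 to 117 ± 12.4 FPKM, the muscle creatine kinase gene Ckm from 0, 0.404 and 0.283 to 101 and 92.4 FPKM and Hand1, a factor of the trophoblast and heart, from 0, 0.995 and 0.430 to 88.6 and 87.7 FPKM. Ddx18 fell from 64.0 ± 3.06 to 42.8 ± 3.75 FPKM.

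At 10 ng/ml, of the 40 tested p53 targets, 33 rose and 7 did not pass (34 higher and 1 lower adjusted over the list alone), with Perp from 12.7 ± 1.28 to 242 ± 20.4 FPKM and the antigen peptide transporter gene Tap1 from 2.30 ± 1.17 to 59.2 ± 3.33 FPKM. The median was 1.37 as deposited and 1.21 rescaled (camera adjusted p = 6.2e-09, adjusted p = 0.022 with an estimated correlation). Cdkn1a and Mdm2, chosen after their values were seen, rose from 29.8 ± 2.58 to 174 ± 6.30 FPKM and from 33.7 ± 0.138 to 236 ± 1.34 FPKM. Among the 30 tested pluripotency genes, 1 rose, 25 fell and 4 did not pass (1 higher and 25 lower adjusted over the list alone). The median was -2.10 as deposited and -2.26 rescaled (camera adjusted p = 4.7e-17, adjusted p = 0.013 with an estimated correlation). Of the 20 tested 2-cell-stage genes, 19 rose and 1 did not pass (19 higher adjusted over the list alone). They include the zinc finger gene Zscan4c (from 2.92 ± 1.76 to 29.7 ± 2.05), one of several copies that can share reads. The median was 2.16 as deposited and 2.05 rescaled (camera adjusted p = 8.6e-06, adjusted p = 0.12 with an estimated correlation). Of the 21 tested trophectoderm genes, 17 rose and 4 did not pass (18 higher adjusted over the list alone). They include Krt18 (from 8.56 ± 5.56 to 255 ± 10.9). The median was 2.14 as deposited and 2.02 rescaled (camera adjusted p = 2.5e-05, adjusted p = 0.065 with an estimated correlation).

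Also at 10 ng/ml, of the 84 tested ribosome biogenesis genes, 11 rose, 43 fell and 30 did not pass (11 higher and 43 lower adjusted over the list alone), with Rrp9 at a log2 change of -1.39 and Tcof1 at -1.23. The median was -0.29 as deposited and -0.45 rescaled (camera adjusted p = 1.1e-06, adjusted p = 0.039 with an estimated correlation). Of the 46 tested large-subunit ribosomal protein genes, 45 fell and 1 did not pass (45 lower adjusted over the list alone). They include Rpl3 (from 716 ± 24.8 to 178 ± 7.59). The median was -0.95 as deposited and -1.12 rescaled (camera adjusted p = 6.0e-21, adjusted p = 0.12 with an estimated correlation). Of the 12 tested PRC2 genes, 2 rose, 8 fell and 2 did not pass (3 higher and 8 lower adjusted over the list alone). They include the accessory subunit genes Jarid2 (from 79.8 ± 9.69 to 12.6 ± 0.509) and E130012A19Rik (from 143 ± 5.17 to 22.01 ± 1.02). The median was -0.48 as deposited and -0.64 rescaled (camera adjusted p = 0.0044, adjusted p = 0.09 with an estimated correlation). Of the 12 tested Hox genes, 10 rose and 2 did not pass (12 higher adjusted over the list alone). They include Hoxc13 (from 4.14 ± 3.04 to 40.2 ± 1.38). The median was 1.32 as deposited and 1.25 rescaled (camera adjusted p = 0.0047, adjusted p = 0.13 with an estimated correlation). Of the 66 tested replication-dependent histone genes, 2 rose, 36 fell and 28 did not pass (2 higher and 36 lower adjusted over the list alone). The median was -0.85 as deposited and -0.98 rescaled (camera adjusted p = 6.6e-10, adjusted p = 0.066 with an estimated correlation).

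At 5 ng/ml, of the 40 tested p53 targets, 33 rose and 7 did not pass (33 higher adjusted over the list alone), with a median of 1.13 as deposited and 0.97 rescaled (camera adjusted p = 4.3e-09, adjusted p = 0.022 with an estimated correlation). Nanog fell from 97.5 ± 7.80 to 3.12 ± 0.0403 FPKM and the thyrotropin-releasing hormone gene Trh from 219 ± 3.46 to 6.05 ± 0.486 FPKM, and among the 30 tested pluripotency genes, 2 rose, 26 fell and 2 did not pass (2 higher and 26 lower adjusted over the list alone). The median was -1.97 as deposited and -2.08 rescaled (camera adjusted p = 4.7e-18, adjusted p = 0.012 with an estimated correlation). The p53 target, pluripotency and ribosome biogenesis lists were the calls that held with an estimated correlation at both doses; at 5 ng/ml, of the 84 tested ribosome biogenesis genes, 7 rose, 37 fell and 40 did not pass (7 higher and 40 lower adjusted over the list alone), with a median of -0.26 as deposited and -0.43 rescaled (camera adjusted p = 1.9e-08, adjusted p = 0.024 with an estimated correlation). Between the doses 428 genes differed, among them Rn18s-rs5, lower at 10 ng/ml by a log2 difference of -2.997 (adjusted p = 0.024), Esrrb (-1.34, adjusted p = 0.0085) and Ckm (1.02, adjusted p = 0.043).

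At 5 ng/ml 7112 of 14522 genes passed (4774 higher, 2338 lower), and at 10 ng/ml 8185 (5280 higher, 2905 lower). The median of all genes was 0.24 as deposited and 0.11 after rescaling at 5 ng/ml and 0.25 as deposited and 0.12 after rescaling at 10 ng/ml. At 5 ng/ml 67.1% of the called genes were higher as deposited and 56.7% after rescaling. At 5 ng/ml the count was 4655 without treated library 5 and 4555 without treated library 6. Both doses were set against the same 3 control libraries: across genes, which are not independent replicates, their changes correlated at r = 0.934, where unchanged groups simulated against shared controls gave 0.402.

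ActD at 10 ng/ml in p53 KO ESCs asked which part of that response needs p53. The titles of these libraries say p53 KO, while their source name is that of the CJ9 ESCs. Without ActD, Perp and, chosen after its values were seen, Cdkn1a stood at 0.807 and 6.20 FPKM here and at 12.7 and 29.8 FPKM in ESCs, which runs the way the titles say. Trp53 rose from 97.9 ± 9.15 to 184 ± 13.5 FPKM with ActD. Rn18s-rs5 fell from 516 ± 198 to 2.79 ± 0.520 FPKM (log2 change -7.04, adjusted p = 0.0019). Jarid2 fell from 92.7 ± 2.67 to 20.1 ± 0.229 FPKM, while the skin protein gene Krtdap rose from 0 and 0.619 to 10.6 and 13.7 FPKM. Nanog, chosen after its values were seen, fell from 113 ± 2.73 to 60.5 ± 2.16 FPKM and Esrrb from 77.6 ± 3.44 to 33.7 ± 3.60 FPKM, and Lefty2 rose from 14.6 ± 2.30 to 62.0 ± 1.63 FPKM. Cdkn1a, chosen after its values were seen, stood at 6.20 ± 0.339 in control and 8.04 ± 0.858 FPKM in treated libraries (adjusted p = 0.12), and Ddx18 at 77.6 ± 1.86 in control and 87.1 ± 0.112 FPKM in treated libraries (log2 change 0.16 as deposited and -0.24 rescaled, adjusted p = 0.15 as deposited).

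Of the 30 tested p53 targets, 8 rose, 1 fell and 21 did not pass (8 higher and 1 lower adjusted over the list alone). They include Btg2 (from 1.54 ± 0.176 to 5.37 ± 1.23) and Perp (from 0.807 ± 0.0523 to 3.22 ± 0.886). The median was 0.33 as deposited and -0.01 rescaled (camera adjusted p = 0.65, adjusted p = 0.77 with an estimated correlation). Among the 30 tested pluripotency genes, 10 rose, 11 fell and 9 did not pass (11 higher and 14 lower adjusted over the list alone). The median was -0.18 as deposited and -0.59 rescaled (camera adjusted p = 1.2e-05, adjusted p = 0.75 with an estimated correlation). Of the 27 tested 2-cell-stage genes, 26 rose and 1 did not pass (27 higher adjusted over the list alone). They include AF067063 (from 0.506 ± 0.123 to 9.78 ± 2.15). The median was 1.63 as deposited and 1.30 rescaled (camera adjusted p = 7.8e-09, adjusted p = 0.56 with an estimated correlation). Of the 84 tested ribosome biogenesis genes, 58 rose and 26 did not pass (64 higher and 1 lower adjusted over the list alone). They include Tsr1 (from 24.8 ± 3.54 to 57.7 ± 5.37). The median was 0.54 as deposited and 0.14 rescaled (camera adjusted p = 1.2e-05, adjusted p = 0.76 with an estimated correlation), and after rescaling 20 rose and 10 fell. Of the 22 tested integrated stress response genes, 2 rose, 13 fell and 7 did not pass (2 higher and 15 lower adjusted over the list alone). They include the serine synthesis gene Psph (from 15.97 ± 0.136 to 6.29 ± 0.585). The median was -0.62 as deposited and -1.003 rescaled (camera adjusted p = 5.6e-13, adjusted p = 0.56 with an estimated correlation).

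The large-subunit ribosomal protein list gave 6 of 46 members lower as deposited (4 adjusted over the list alone) and 35 rescaled, with Rpl3 from 615 ± 42.2 to 281 ± 9.73 FPKM and a median of -0.05 as deposited and -0.46 rescaled (camera adjusted p = 8.6e-09, adjusted p = 0.76 with an estimated correlation). Of 13145 genes tested, 4870 passed, 4301 higher and 569 lower. The median of all genes was 0.35 as deposited and 0.01 after rescaling, and 88.3% of the called genes were higher as deposited and 43.4% after rescaling. Many calls held without control library 22, and almost none without treated library 15 or 16. Such a fit leaves 1 library in a group, so calls lost there do not tell dependence on a library from the smaller design.

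In the test of the difference, 5684 of 15013 genes responded differently to 10 ng/ml ActD in ESCs and in p53 KO ESCs (2619 above and 3065 below in ESCs). Log2 changes in ESCs and in p53 KO ESCs were -5.13 against -0.89 (adjusted p = 2.6e-05) for Nanog, -4.97 against -0.17 (adjusted p = 9.7e-06) for Tdgf1, 4.15 against 1.21 (adjusted p = 1.0e-04) for Perp, 4.89 against 0.58 (adjusted p = 9.5e-04) for Krt18 and 5.97 against 1.16 (adjusted p = 3.8e-04) for Hand1. For Pou5f1 and Cdkn1a, chosen after their values were seen, they were -3.08 against 0.23 (adjusted p = 1.2e-05) and 2.51 against 0.33 (adjusted p = 7.2e-05). The pluripotency network lay lower in ESCs by a median difference of -2.02 (camera adjusted p = 4.3e-14, adjusted p = 0.0077 with an estimated correlation), with 26 of 30 members called below and 1 above. The p53 targets lay higher in ESCs by 1.23 (camera adjusted p = 3.3e-10, adjusted p = 0.0077 with an estimated correlation), and ribosome biogenesis differed by -0.81 (camera adjusted p = 9.8e-13, adjusted p = 0.08 with an estimated correlation). For the 2-cell-stage list the difference was 0.11 (camera adjusted p = 0.39, adjusted p = 0.65 with an estimated correlation) and did not pass; it was 0.33 rescaled, 0.45 at a minimum of 5 FPKM and 1.29, which passed, with a pseudocount of 0.1. Genotype and table coincide here too.

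**Figure D2:**
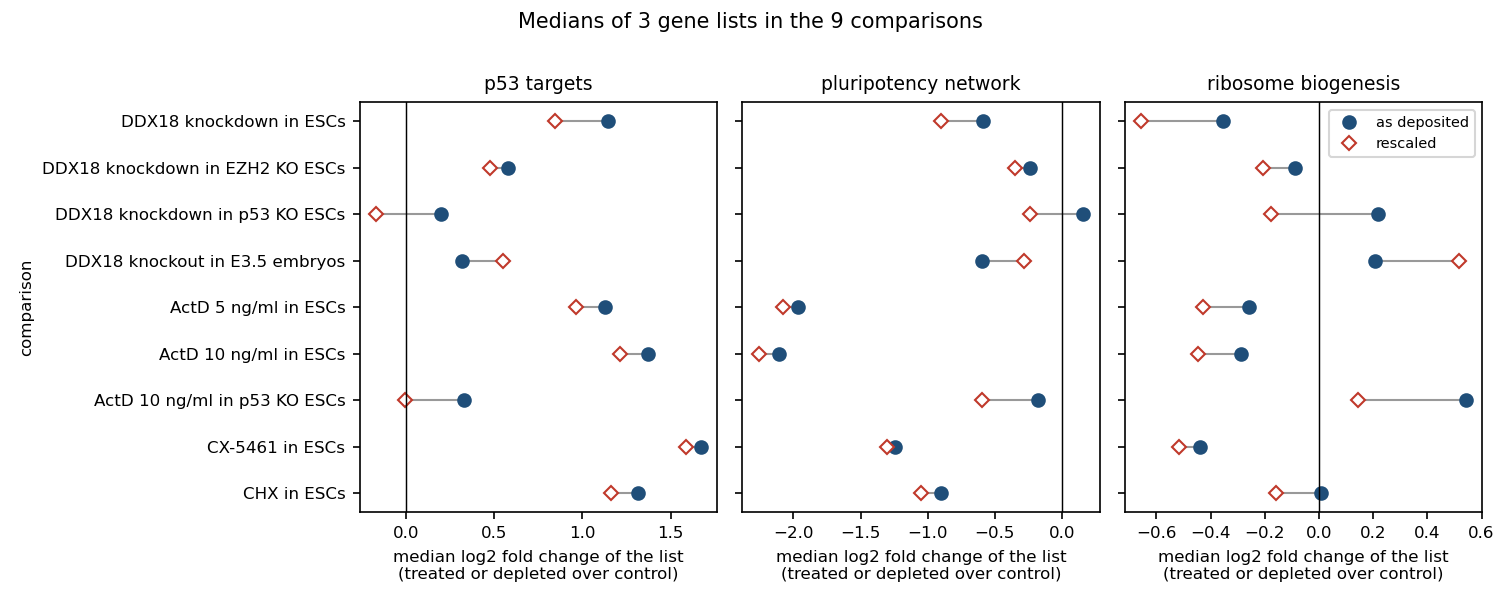
Median log2 change of the p53 target, pluripotency network and ribosome biogenesis lists in the 9 comparisons, as deposited (filled circles) and after rescaling (open diamonds), without error bars. The p53 targets stood at 1.67 with CX-5461 and 1.37 with ActD at 10 ng/ml, and their median changed sign on rescaling with ActD (0.33 to -0.01) and with knockdown (0.20 to -0.17) in p53 KO ESCs.

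CX-5461 gave a further block of RNA polymerase I. Perp rose from 7.75 ± 0.240 to 229 ± 1.72 FPKM (log2 change 4.71, adjusted p = 2.4e-08), Krt8 from 1.46 ± 0.525 to 62.0 ± 1.74 FPKM and S100a6 from 3.45 ± 0.287 to 106 ± 1.23 FPKM. The stress response gene Nupr1 fell from 17.3 ± 2.59 to 1.56 ± 1.10 FPKM. Ddx18 fell from 12.2 ± 0.533 to 6.57 ± 0.548 FPKM and Ezh2 from 6.96 ± 0.531 to 3.19 ± 0.372 FPKM. Among genes chosen after their values were seen, Nanog fell from 126 ± 6.17 to 41.1 ± 2.64 FPKM, Cdkn1a rose from 9.31 ± 1.10 to 69.7 ± 1.05 FPKM, and Rn18s-rs5 fell from 88.3 ± 15.4 to 50.5 ± 4.88 FPKM (adjusted p = 0.0015).

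Of the 23 tested 2-cell-stage genes, 23 rose (23 higher adjusted over the list alone). They include Zscan4f (from 1.29 ± 0.558 to 21.0 ± 1.49) and Tcstv3 (from 0, 0 and 0.223 to 9.01, 8.22 and 10.6). The median was 2.51 (camera adjusted p = 5.3e-12, adjusted p = 0.028 with an estimated correlation), and this list was the only call with CX-5461 that held with an estimated correlation. Of the 39 tested p53 targets, 32 rose and 7 did not pass (33 higher adjusted over the list alone). They include Btg2 (from 4.27 ± 0.324 to 67.1 ± 1.21) and Plk2 (from 1.90 ± 0.0703 to 30.4 ± 0.0608). The median was 1.67 (camera adjusted p = 5.3e-12, adjusted p = 0.08 with an estimated correlation). Among the 30 tested pluripotency genes, 27 fell and 3 did not pass (28 lower adjusted over the list alone). They include Zfp42 (from 311 ± 29.5 to 70.7 ± 7.32). The median was -1.24 (camera adjusted p = 1.1e-11, adjusted p = 0.21 with an estimated correlation). Of the 82 tested ribosome biogenesis genes, 5 rose, 54 fell and 23 did not pass (6 higher and 57 lower adjusted over the list alone). They include Nolc1 (from 46.5 ± 1.79 to 22.7 ± 0.753). The median was -0.44 (camera adjusted p = 2.7e-08, adjusted p = 0.21 with an estimated correlation).

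Of the 19 tested genes of the RNA polymerase I machinery, 3 rose, 10 fell and 6 did not pass (3 higher and 10 lower adjusted over the list alone). They include the rDNA transcription factor gene Ubtf (from 15.1 ± 1.30 to 7.66 ± 0.575). The median was -0.22 (camera adjusted p = 0.056, adjusted p = 0.21 with an estimated correlation). Of the 13 tested snoRNA host genes, 11 fell and 2 did not pass (11 lower adjusted over the list alone). They include Snhg5 (from 51.7 ± 3.82 to 15.99 ± 0.777). The median was -0.68 (camera adjusted p = 1.6e-04, adjusted p = 0.08 with an estimated correlation). Of 12966 genes tested, 8011 passed, 4263 higher and 3748 lower, and 53.2% of the called genes were higher as deposited and 47.1% after rescaling.

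CHX was the other treatment set beside the knockdown. The histone genes Hist1h2bc and Hist3h2a rose from 4.20 ± 0.781 to 282 ± 13.4 FPKM and from 0.768 ± 0.669 to 68.9 ± 1.14 FPKM, and Gadd45g, a growth arrest gene, from 0.844 ± 0.266 to 56.5 ± 2.28 FPKM. The Nodal pathway genes Lefty1 and Tdgf1 fell from 32.7 and 30.99 to 0.354 and 0 FPKM and from 292 ± 18.8 to 15.1 ± 0.00700 FPKM. Among genes chosen after their values were seen, Nanog fell from 106 ± 5.65 to 13.9 ± 2.36 FPKM, while Pou5f1 stood at 332 ± 23.1 in control and 354 ± 8.08 FPKM in treated libraries (adjusted p = 0.32) and Rn18s-rs5 at 289 ± 48.3 in control and 243 ± 16.01 FPKM in treated libraries (adjusted p = 0.17). Trp53 rose from 253 ± 15.0 to 450.3 ± 12.7 FPKM, Ddx18 fell from 67.5 ± 2.85 to 49.6 ± 3.17 FPKM, and Ezh2 stood at 45.4 ± 0.405 in control and 50.9 ± 5.36 FPKM in treated libraries (log2 change 0.16 as deposited and -0.01 rescaled, adjusted p = 0.21 as deposited).

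Of the 68 tested replication-dependent histone genes, 66 rose and 2 did not pass (66 higher adjusted over the list alone). The median was 1.89 as deposited and 1.73 rescaled (camera adjusted p = 1.1e-16, adjusted p = 0.39 with an estimated correlation). Of the 39 tested p53 targets, 33 rose, 2 fell and 4 did not pass (33 higher and 2 lower adjusted over the list alone). They include Plk2 (from 16.5 ± 0.475 to 101 ± 1.28) and the secreted factor gene Gdf15 (from 5.16 ± 0.252 to 32.2 ± 2.15). The median was 1.32 as deposited and 1.16 rescaled (camera adjusted p = 8.7e-09, adjusted p = 0.39 with an estimated correlation). Among the 30 tested pluripotency genes, 4 rose, 22 fell and 4 did not pass (4 higher and 22 lower adjusted over the list alone). They include Zfp42 (from 349.9 ± 0.301 to 36.4 ± 2.75). The median was -0.90 as deposited and -1.05 rescaled (camera adjusted p = 1.8e-07, adjusted p = 0.39 with an estimated correlation). Of the 13 tested mitochondrially encoded genes, 11 fell and 2 did not pass (13 lower adjusted over the list alone). They include mt-Nd1 (from 3286 ± 169 to 638 ± 93.6). The median was -1.49 as deposited and -1.66 rescaled (camera adjusted p = 9.5e-07, adjusted p = 0.39 with an estimated correlation).

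Of the 84 tested ribosome biogenesis genes, 31 rose, 19 fell and 34 did not pass (31 higher and 20 lower adjusted over the list alone). They include Nle1 (from 13.7 ± 1.38 to 35.1 ± 1.59). The median was 0.01 as deposited and -0.16 rescaled (camera adjusted p = 0.73, adjusted p = 0.75 with an estimated correlation), with camera pointing down. Of 13257 genes tested, 7026 passed, 4401 higher and 2625 lower. The median of all genes was 0.12 as deposited and -0.02 after rescaling, and 62.6% of the called genes were higher as deposited and 50.9% after rescaling. The count was 4173 without treated library 20 and 4307 without treated library 21.

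The knockdown in ESCs was then set against every other comparison across the genes tested in both, which are not independent replicates. Log2 changes correlated at r = 0.838 with CX-5461, 0.816 and 0.791 with ActD at 5 and 10 ng/ml, 0.794 with knockdown in EZH2 KO ESCs, 0.539 with CHX, 0.505 with knockdown in p53 KO ESCs, 0.248 with ActD in p53 KO ESCs and 0.0759 with knockout embryos. With CX-5461, 88.0% of 4030 genes had the same sign, with 1656 genes higher in both (950.0 if independent) and 1237 lower in both (591 if independent). In embryos 54.6% of 2418 genes had the same sign, with 6 genes higher in both (7.70 if independent) and 78 lower in both (65.5 if independent), and 51 genes were called in opposite directions. The correlations were not tested against each other.

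CLIP-seq and TAP-seq asked which RNAs DDX18 binds in ESCs. Regions annotated as ribosomal RNA numbered 148 and 150 in the 2 CLIP libraries and 152 and 152 in the 2 TAP libraries, of 880, 939, 635 and 741 regions in all. Their share of the summed region score was 90.0% and 88.9% in the 2 CLIP libraries and 86.5% and 84.9% in the 2 TAP libraries, with covered lengths over all regions of 161600, 173900, 119000 and 137700 bases. Repeats of the large-subunit ribosomal RNA made up most of that, with 92, 92, 93 and 92 regions and 83.6%, 82.9%, 80.9% and 79.0% of the score. The region with the highest score in the first CLIP library lay on chromosome 9 from 3258801 to 3258900 in mm10, in such a repeat, with scores of 515424, 533267, 221142 and 188498. The region over Rn45s, the 45S precursor of ribosomal RNA, lay on chromosome 17 from 39842901 to 39848800 and scored 76443, 79949.8, 32660.5 and 34081. Reads of near-identical ribosomal RNA copies cannot be assigned to 1 of them.

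Regions annotated to small nucleolar RNAs numbered 84 and 93 in CLIP and 89 and 100 in TAP. They held 0.09% to 0.20% of the score, and some lay outside the gene. Small nuclear RNA regions (44 and 47 in CLIP, 44 and 51 in TAP) held 0.19% to 0.43% of the score. Repeats of U3, itself a small nucleolar RNA but outside the class above, held 0.16% to 0.37%. At least 1 base was shared with the other library of the pair by 83.8% and 78.5% of the regions in the 2 CLIP libraries and 89.6% and 76.5% in the 2 TAP libraries. Between the first libraries of each kind it was 89.0% of TAP and 63.1% of CLIP regions. The meaning of the authors' scores is not given, and no control library was analysed here, so these shares have no measured background.

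**Figure D3:**
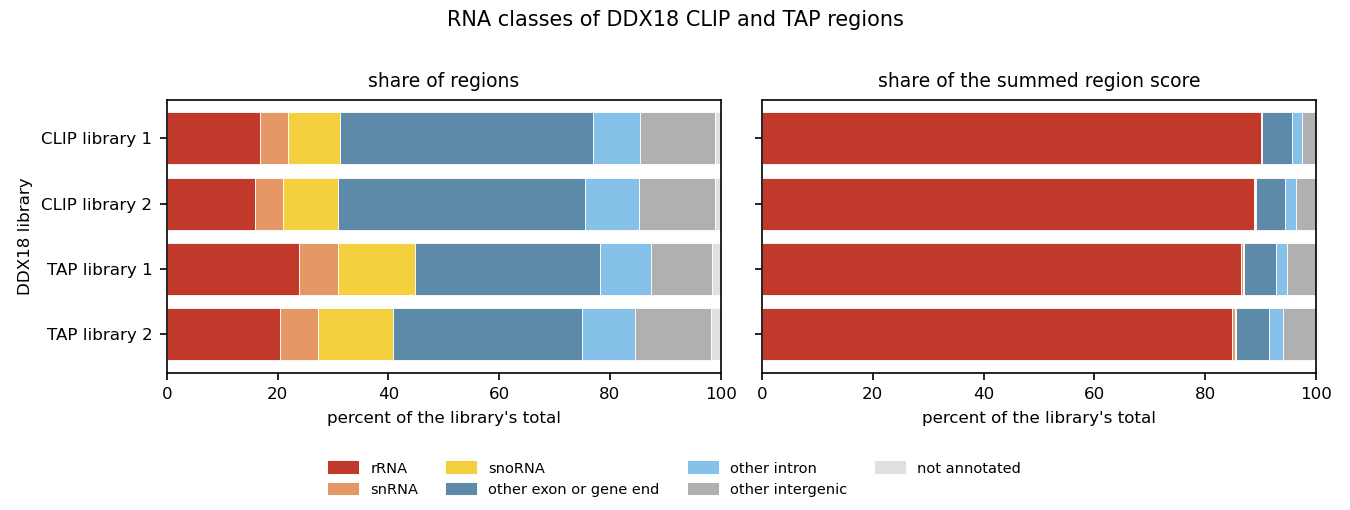
Share in percent of regions and of summed region score by RNA class in each of the 2 CLIP and 2 TAP libraries of DDX18. Ribosomal RNA takes 16.8% of regions and 90.0% of the summed score in the first CLIP library.

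ChIP-seq asked where DDX18 sits on DNA, with 1 library of tagged DDX18 and 1 of control cells, so no difference between them has a replicate check. The authors' list held 1076 regions, and 1 of them stood apart: on chromosome 17 from 39979838 to 39985882, 6045 bases wide, it held 1581 tags with a fold enrichment of 6.17 and a false discovery rate of 0%. The other 1075 regions had a false discovery rate of 100%, a median of 6 tags over all regions and at most 22 tags. The reverse list, control over DDX18, held 2491 regions, with 397 tags at the mitochondrial genome from 14 to 6538 (fold 10.4) and 988 tags on chromosome 2 from 98506280 to 98507612 (fold 2.27). The build of these coordinates is not given in the sources used here; a region ending at 196711460 on chromosome 1 lies beyond the last gene end of 195291439 in the mm10 annotation. The wide region is about as wide as the Rn45s region of the CLIP libraries, and whether they are the same place was not settled.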

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

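The test of single p53 KO libraries was set before its result was seen, while its bars of 2 and then 1 bootstrap SD, tried in turn, and the tests of the gene selection and of the p53 genotype were chosen after it. A test of the difference between 2 genotypes pointed to each result given here. Under knockdown ESCs differed from p53 KO ESCs in 1164 selected genes and from EZH2 KO ESCs in 987. EZH2 KO differed from p53 KO ESCs in 178. Under 10 ng/ml ActD ESCs differed from p53 KO ESCs in 5684.

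Under knockdown, the median difference of ESCs minus p53 KO ESCs was 0.89 (adjusted p = 0.037 with an estimated correlation) for the p53 targets and 1.06 (adjusted p = 0.15 with an estimated correlation) for the 2-cell-stage genes. It was -0.50 (adjusted p = 0.24 with an estimated correlation) for ribosome biogenesis. For ESCs minus EZH2 KO ESCs it was 0.51 (adjusted p = 0.13 with an estimated correlation) for the p53 targets and 0.67 (adjusted p = 0.13 with an estimated correlation) for the 2-cell-stage genes. The same difference was -0.30 (adjusted p = 0.18 with an estimated correlation) for the pluripotency network and -0.23 (adjusted p = 0.23 with an estimated correlation) for ribosome biogenesis. For EZH2 KO minus p53 KO ESCs it was 0.80 (adjusted p = 0.4 with an estimated correlation) for the 2-cell-stage genes and 0.35 (adjusted p = 0.091 with an estimated correlation) for the p53 targets, against 1.59 and 0.20 with a pseudocount of 0.1. With that pseudocount the 2-cell-stage genes differed by 1.63 from p53 KO and 0.36 from EZH2 KO ESCs, and rescaled the 4 differences from EZH2 KO ESCs were 0.32, 0.44, -0.49 and -0.42. Under ActD, the difference of ESCs minus p53 KO ESCs was 1.23 (adjusted p = 0.0077 with an estimated correlation) for the p53 targets and -0.81 (adjusted p = 0.08 with an estimated correlation) for ribosome biogenesis.

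The pluripotency network differed under knockdown by a median of -0.76 (adjusted p = 0.24 with an estimated correlation), lower in ESCs than in p53 KO ESCs, with Nanog at -0.81 against 0.81. A single p53 KO library stays open as a cause. Without 1 library the median of the 17 genes in p53 KO ESCs (-0.15) ran from -0.24 to 0.21. A sign change was set beforehand to count for that cause. Here it led away from ESCs (-0.59), but for all 30 tested genes (0.16 to -0.05) towards them. The 17-gene median stayed above ESCs by 0.34 or more (bootstrap SD 0.29), the outcome against that cause. Selection of the genes in the ESC knockdown table stays open. Between EZH2 KO and p53 KO ESCs, whose tables hold all genes, the list differed by -0.44 (adjusted p = 0.270 with camera), and by -0.17 rescaled. The p53 genotype is a candidate explanation. The ActD tables, from other libraries, differed by a median of -2.02 for the same list (adjusted p = 0.0077 with an estimated correlation). Genotype and table coincide in each, so a difference between tables remains open too.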

How the results depend on the processing

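The knockdown table's selection rule, the crossed pairing and the comparison of the EZH2 KO with the p53 KO knockdown were chosen after seeing the data. Counts of called genes stayed within 1.5 times the reported count in 57 of the alternatives and moved further in 39. Of the list medians under alternatives, 982 kept their direction and their side of the threshold, 28 no longer passed and 20 changed sign. Of the values of named genes, 6597 kept both, 1222 no longer passed, 6 newly passed and 17 changed sign. Where a result changed, the cause was not tested, except that leaving out a library leaves fewer samples and a filter changes the genes tested. The smallest library of known depth held 7112852 mapped reads, and depth is unknown for the embryo, CX-5461 and both knockout-line knockdown tables. Intervals cover counting error only. The count models planned for count tables were not run, since the tables hold FPKM.

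Genes called by limma in embryos numbered 3 with a pseudocount of 0.1, 0 with no filter (2756 at an unadjusted p under 0.05), 259 with no variance trend and 126 rescaled. With CX-5461 they numbered 5104 at a minimum of 5 FPKM, and with ActD in p53 KO ESCs 2271 with no filter and 3063 rescaled. With knockdown in p53 KO ESCs the count was 0 with a pseudocount of 0.1, no filter or no trend (3536, 4009 and 3585 at an unadjusted p under 0.05), 868 at a minimum of 5 FPKM and 151 rescaled. With knockdown in EZH2 KO ESCs it was 56 with no filter and 438 with no trend. The selection rule of the knockdown table gave 1506 genes in embryos, 2320 with knockdown in p53 KO ESCs and 2226 in EZH2 KO ESCs, where the highest other split of the libraries gave 315, 470 and 449.

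The replicate number as a block gave 725 genes in embryos, 0 with knockdown in p53 KO ESCs (2880 at an unadjusted p under 0.05), 4550 in ESCs, 898 in EZH2 KO ESCs and 7829 with CX-5461. Libraries with the same number did not deviate together (correlations 0.03 in embryos, -0.01 in ESCs, -0.05 in EZH2 KO ESCs and at most 0.04 with CX-5461), so the numbers were not used to pair libraries. In p53 KO ESCs the correlation was -0.26, and the crossed pairing as a block called 1149 genes. No paired analysis was possible because the columns carry no shared replicate numbers for ActD, CHX and ActD in p53 KO ESCs.

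After rescaling, list medians changed sign for ribosome biogenesis with CHX (-0.16), p53 targets with ActD in p53 KO ESCs (-0.00670) and, with knockdown in p53 KO ESCs, p53 targets (-0.17), the pluripotency network (-0.24), ribosome biogenesis (-0.18) and histone genes (-0.39). Ribosome biogenesis with ActD in p53 KO ESCs no longer passed (0.14). Among genes, Trp53 with knockdown in ESCs (-0.13), Trp53 (-0.11) and Actb (-0.0179) at 5 ng/ml ActD, Ezh2 with CHX (-0.0104) and Ddx18 (-0.24) and Snhg5 (-0.0184) with ActD in p53 KO ESCs changed sign. So did, among genes chosen after their values were seen, Pou5f1 with CHX (-0.0744), Cdkn1a with ActD in p53 KO ESCs (-0.0357) and Pou5f1 with knockdown there (-0.0417). With no filter, trophectoderm (-0.69) and large-subunit ribosomal proteins (0.0606) in embryos, Hox genes with CHX (0.17) and Hox genes with knockdown in p53 KO ESCs (0.38) no longer passed, and histone genes there changed sign (-0.00688). At a minimum of 5 FPKM, trophectoderm (-0.91), large-subunit ribosomal proteins (0.0544) and the RNA polymerase I machinery (0.18) in embryos no longer passed. The mesoderm list no longer passed at 5 ng/ml ActD with a pseudocount of 0.1 (2.49) or that minimum (2.15), nor at 10 ng/ml (2.87 and 2.15).

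The difference between EZH2 KO and p53 KO knockdowns took in 94 genes with a pseudocount of 0.1 and 365 at a minimum of 5 FPKM. The list difference of the pluripotency network between ESCs and p53 KO ESCs (-0.76 at that minimum) and of the 2-cell-stage genes between ESCs and EZH2 KO ESCs (0.36 with that pseudocount) no longer passed. That of the 2-cell-stage genes under ActD newly passed (1.29 with that pseudocount). Rescaled, ribosome biogenesis differed by -0.01 between EZH2 KO and p53 KO ESCs. Correlations across genes with the ESC knockdown, each with a pseudocount of 0.1 and at a minimum of 5 FPKM, were 0.0386 and 0.0426 for embryos, 0.797 and 0.844 for 5 ng/ml ActD, 0.782 and 0.821 for 10 ng/ml and 0.839 and 0.864 for CX-5461. They were 0.563 and 0.563 for CHX, 0.246 and 0.311 for ActD in p53 KO ESCs, 0.490 and 0.582 for knockdown in p53 KO ESCs and 0.774 and 0.836 in EZH2 KO ESCs. Rescaled, they were 0.0529, 0.822, 0.799, 0.842, 0.548, 0.285, 0.522 and 0.798 in the same order.

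In tables with 2 libraries per group, leaving out 1 leaves a lone library that is assumed to vary like the other groups. Without 1 library the counts ran from 0 to 1 in embryos, 4555 to 8729 at 5 ng/ml ActD, 4173 to 4884 with CHX, 2 to 3769 with ActD in p53 KO ESCs, 0 to 0 with knockdown there and 0 to 351 in EZH2 KO ESCs. Medians of lists that changed sign or no longer passed without some library ran from -1.13 to -0.66 for trophectoderm, 0.0617 to 0.32 for the RNA polymerase I machinery, 0.0969 to 0.57 for mitochondrially encoded genes and -0.0514 to 0.19 for large-subunit ribosomal proteins in embryos. They ran from 0.93 to 1.13 for mesoderm at 5 ng/ml ActD, -0.0231 to 0.0137 for ribosome biogenesis with CHX and -0.17 to 0.0727 for large-subunit ribosomal proteins with ActD in p53 KO ESCs. With knockdown in p53 KO ESCs they ran from -0.59 to 0.00668 for 2-cell-stage, 0.86 to 0.96 for Hox, -0.22 to 0.15 for S-phase, -0.95 to -0.0261 for fibroblast, -0.0468 to 0.44 for pluripotency and -0.38 to 0.27 for histone genes. In EZH2 KO ESCs they ran from -0.18 to -0.0956 for the RNA polymerase I machinery, -0.33 to -0.0338 for mitochondrially encoded and -0.19 to 0.00163 for histone genes. Trp53 ran from -0.00101 to 0.13 at 5 ng/ml ActD, Pou5f1 from -1.11 to 0.20 in embryos, and Ezh2 from -0.47 to 0.82 in embryos, -0.17 to 0.0965 with ActD in p53 KO ESCs and -0.26 to 0.12 with knockdown in EZH2 KO ESCs.

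A false discovery rate of at most 5% left 1 ChIP-seq region and a fold enrichment of at least 10 left 1075, the wide region not among them. Among regions with a score at or above their library's median, 408 of the first CLIP library were shared with the second and 309 of the first TAP library, against 737 and 569 of all regions, as that setting removes regions. The ribosomal RNA percent by length covered was 24.6, 23.4, 34.9 and 29.3 in the CLIP and then the TAP libraries, and among the regions with those scores 31.3, 29.8, 43.2 and 38.6.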

Other observations

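All the tests of explanations in this part were chosen after the result was seen. With 10 ng/ml ActD in ESCs, of the 14 tested mesoderm and primitive streak genes, 12 rose and 2 fell (12 higher and 2 lower adjusted over the list alone), with the signalling gene Wnt3 from 0.109 ± 0.0567 to 13.4 ± 0.00226 FPKM and Bmp4, lower, from 11.9 ± 1.24 to 1.13 ± 0.0806 FPKM. The median was 1.42 as deposited and 1.31 rescaled (camera adjusted p = 0.025, adjusted p = 0.16 with an estimated correlation). Of the 22 tested immediate early genes, 17 rose, 4 fell and 1 did not pass (17 higher and 4 lower adjusted over the list alone). They include the AP-1 genes Fosl1 (from 2.08 ± 0.415 to 151 ± 7.86) and Jun (from 3.56 ± 1.71 to 45.2 ± 1.74). The median was 1.89 as deposited and 1.75 rescaled (camera adjusted p = 7.7e-04, adjusted p = 0.065 with an estimated correlation). Of the 15 tested neuroectoderm and epiblast genes, 9 rose, 4 fell and 2 did not pass (9 higher and 4 lower adjusted over the list alone). They include Nes, which encodes nestin (from 2.20 ± 0.719 to 21.1 ± 0.939). The median was 0.80 as deposited and 0.72 rescaled (camera adjusted p = 0.6, adjusted p = 0.61 with an estimated correlation). Of the 16 tested primitive and parietal endoderm genes, 10 rose, 5 fell and 1 did not pass (10 higher and 5 lower adjusted over the list alone). They include the laminin gene Lama1 (from 6.50 ± 0.526 to 1.58 ± 0.244). The median was 0.83 as deposited and 0.69 rescaled (camera adjusted p = 0.67, adjusted p = 0.67 with an estimated correlation).

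At the same dose, of the 20 tested apoptosis regulators, 11 rose, 2 fell and 7 did not pass (12 higher and 2 lower adjusted over the list alone), with the proapoptotic gene Bcl2l11 from 3.35 ± 1.05 to 11.4 ± 0.352 FPKM. The median was 0.55 as deposited and 0.40 rescaled (camera adjusted p = 0.39, adjusted p = 0.41 with an estimated correlation). Of the 8 tested fibroblast markers, 6 rose, 1 fell and 1 did not pass (7 higher and 1 lower adjusted over the list alone). They include Vim, which encodes vimentin (from 50.02 ± 5.69 to 250.3 ± 0.447), and the fibronectin gene Fn1 (from 137 ± 2.72 to 33.2 ± 0.752). The median was 0.99 as deposited and 0.89 rescaled (camera adjusted p = 0.16, adjusted p = 0.28 with an estimated correlation). The blood cell, oocyte and Y-linked or Xist lists had 1, 1 and 3 tested members, too few for a list test. Among them were Hba-a2, higher (from 0, 0.454 and 0.472 to 2.11 and 1.27), the zona pellucida gene Zp3, lower (from 10.3 ± 3.01 to 1.65 ± 0.587) and Xist, higher (log2 change 1.44).

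Of the 450 genes called in knockout embryos, 395 were lower. Weakly expressed genes missed in the knockout libraries stay open: of the called genes at 5 FPKM or more in both knockout libraries 74.3% were lower as deposited but 34.4% rescaled. The scaling of the deposited values stays open: after rescaling 42 of 126 called genes were higher (33.3%, upper 95% Wilson bound 41.9%). Fewer inner cell mass cells in the knockout embryos may add to it, and the pluripotency list's median less that of the trophectoderm list, 0.37 with a bootstrap SD of 0.65, does not decide. Loss of DDX18 itself and a difference in RNA quality, for which no test was made, stay open as well.

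The wide ChIP-seq region on chromosome 17 had a fold enrichment of 6.17 over the control library. Many ribosomal DNA copies collapsed onto 1 place stay open, since these libraries do not load all multi-copy DNA alike: the mitochondrial genome had a fold of 10.4 in the reverse comparison. A random gain of reads in either library stays open: 0 regions of the reverse comparison had at least its width and tags together, but 1 mitochondrial region there was wider (6525 bases). Enrichment with DDX18 may account for it, as a hypothesis from 1 library per group, and a background of the biotin pulldown that differs between the tagged and the control cells was not tested. For CX-5461, 3 libraries against 3 make 10 splits, too few for a share under 0.05: 1 split, the real one, called 8011 genes, and the highest other called 2.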
